A study of Mus musculus with 6 samples.

How the data were processed

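RNA was measured by bulk RNA sequencing in 6 tumours that the labels describe as grown from NA13, a mouse bladder cancer cell line, with the strain given as C57BL/6. Per the labels, 3 tumours carried a scrambled shRNA and 3 an shRNA against Ddr2, and all 6 received IgG. Messenger RNA was selected with poly-T beads and sequenced as paired-end reads of 150 bp, per the labels' protocols. The samples are whole tumours, so each library mixes RNA of tumour cells and of host cells. The labels do not say whether samples of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

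The submitters' processing notes name RSEM 1.2.31, Bowtie2 2.1.0, limma without a version, and the genome build GRCm38.p5, without saying which step each was used for. The authors deposited a table of whole-number counts per Entrez gene, which may be rounded estimates, since the tool named can give estimated counts. That table lists 15295 genes, and its lowest count in any library is 1, so genes with a count of 0 in some library are not analysed here. In it, 17 values of 100000 or more are written with 3 significant digits. The authors also deposited log2 values, as a table of the series and again as a file per sample. Checked against the counts, these are the log2 of the count divided by 1 factor per library, plus 1. Undoing that step gave whole numbers in 100% of values within 0.05, of which 91753 equalled the deposited count and 17 differed. The annotation, the gene filter, the strand setting and the treatment of reads shared between near-identical genes are not given in the sources used here. Values of genes with close copies, such as Myh4, Acta1 and Lce1a1, and of genes that overlap another gene or its antisense partner, are therefore uncertain.

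Gene symbols were taken from a RefSeq table of the mouse assembly by Entrez number, and 14876 numbers matched while 419 did not. Coordinates are those of GENCODE M21 on GRCm38. The deposited files hold no coordinates.

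The counts were used as deposited. Library totals ranged from 15560571 to 19522985 counts. Genes were filtered with filterByExpr, which left 14498 genes, libraries were scaled by TMM, and the groups were compared with the quasi-likelihood F test of edgeR 4.0.16 with robust fitting in R 4.3.3. P-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Gene levels are given as CPM, the usual count scaled to a common library total, with TMM-scaled totals. The 95% interval of a log2 fold change reached 0.76 to either side in the median gene, and the common biological coefficient of variation was 35.3%. Intervals on single counts are exact Poisson intervals, which cover counting error only.

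There were 29 gene lists, fixed before the data were examined, as were the main tests, the alternatives first listed and the rule for naming genes. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. Each needed at least 5 tested members, which left 28 lists over which p-values were adjusted. The erythrocyte list had 4 tested members and was not tested. Exact permutation tests of a difference between the groups are two-sided over all assignments of 3 and 3 libraries, and cannot give a p below 0.1. Those of Ddr2 against list means are over 720 pairings of the 6 libraries, or over 8 exchanges within pairs.

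The genes named are Ddr2 and Ddr1, genes past the threshold, the next 5 in each direction by unadjusted p, the members of each list with the smallest p, and the 2 most abundant skeletal muscle genes. Genes next by p needed an average log2 CPM of at least 1, no overlap between the groups, and a symbol other than that of a predicted gene. The rule allows up to 4 members per list. The numbers used, 3 for a called list and 1 for another, were set after values had been seen.

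The test was tried on simulated counts for the comparison of the 2 groups, with 200 of 14360 genes changed and the measured spread. It called 10.3% of genes changed by 1 on the log2 scale, 81.8% of those changed by 2 and 97.0% of those changed by 3. The changed genes all had an average log2 CPM above 1. Each gene was simulated independently of the others, so these shares may exceed those in the real counts. Of 143 calls, 18 (12.6%) were of unchanged genes, which is above the 5% aimed at, in 1 simulated data set.

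Replicate numbers come from the sample titles. Deviations from the group means correlated across genes between same-numbered libraries of the groups, with r of 0.299, 0.267 and 0.253 for numbers 1, 2 and 3. All exceeded 0.1, which was the criterion set for treating the numbers as pairs. The labels do not say what a shared number stands for, and control 3 with the library labelled shDdr2 2 gave 0.254. No pair of libraries within a group agreed within counting noise, with chi-square per degree of freedom from 24.8 to 229.

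Alternatives were other scalings, other count filters, DESeq2 1.42.0, limma on voom weights and on the deposited log2 values, non-robust fitting, a replicate block, other list tests, and leaving out each library in turn. Alternatives chosen after seeing the data were counts with all digits recovered from the log2 values, leaving out replicate 1 of both groups, the mean of the collagen list as a covariate, and an estimated correlation with libraries left out.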

Results

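The transcriptomes of 6 tumours grown from NA13 mouse bladder cancer cells were compared, 3 with a scrambled shRNA (control) and 3 labelled as carrying an shRNA against Ddr2. Ddr2 encodes discoidin domain receptor 2, a collagen-binding receptor tyrosine kinase, and the series describes NA13 as a line with high DDR2 expression. The comparison asks which genes and cell type markers differ in whole tumours between the shRNAs. The total counts were 18917186, 16144741 and 15560571 in control 1 to 3, and 15976000, 19522985 and 16523499 in the libraries labelled shDdr2 1 to 3.

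Ddr2 itself was not lower in the libraries labelled shDdr2. Ddr2 (Entrez 18214, a protein-coding gene at chromosome 1, 169972307 to 170110762, minus strand, GRCm38) stood at 14.5 ± 7.28 CPM in control tumours and at 17.5 ± 12.0 CPM in tumours labelled shDdr2 (SD, n = 3 each). Its level was 6.42, 16.7 and 20.5 CPM in control 1 to 3, from 119, 279 and 326 counts. In the libraries labelled shDdr2 it was 4.84, 18.9 and 28.6 CPM, from 67, 389 and 498 counts. The fitted log2 fold change was 0.27 (SE 0.66, 95% interval -1.27 to 1.81), with an unadjusted edgeR p of 0.694. An exact permutation test of the log2 CPM gave p = 0.9, where 0.1 is the smallest possible. The difference was -0.08 without control 1, -0.28 without the library labelled shDdr2 3, 0.60 without control 3 and 0.71 without the library labelled shDdr2 1. Its paralogue Ddr1, the collagen receptor of epithelia, was at 208 ± 15.3 and 226 ± 62.0 CPM (SD, n = 3), a log2 fold change of 0.12 (SE 0.25) that was -0.07 without the library labelled shDdr2 2 and 0.32 without that labelled shDdr2 1. The level of the target gene thus did not bear out the labels in these whole tumours. It did not contradict them either, since the interval includes a lower level in the libraries labelled shDdr2. Every direction given here is between libraries as labelled.

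**Figure D1:**
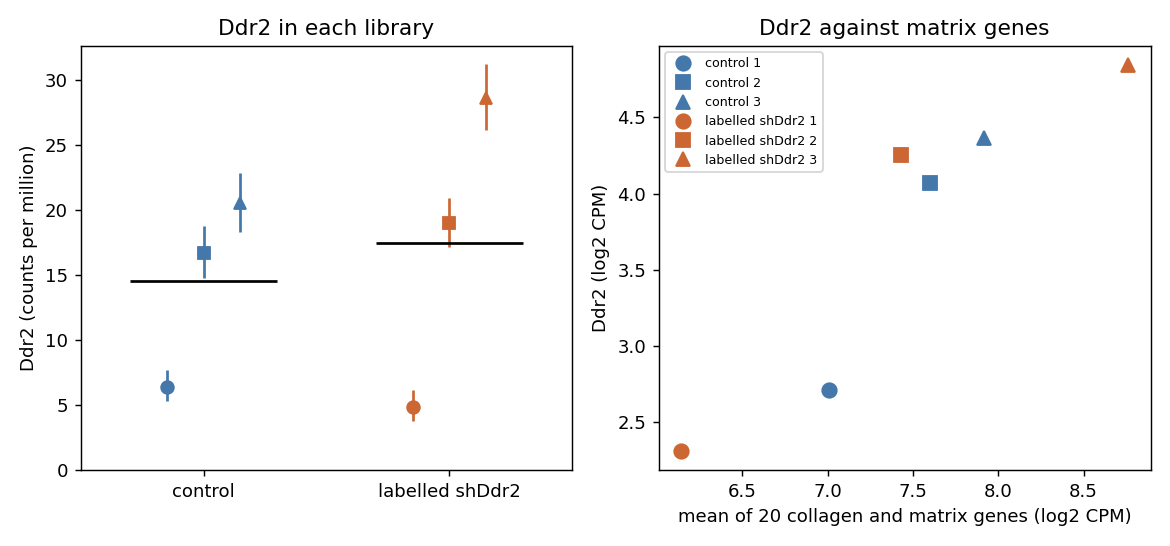
Left, Ddr2 in CPM in each library, with exact Poisson 95% intervals for counting error and a line at each group's mean; right, Ddr2 against the mean of 20 collagen and matrix genes, both in log2 CPM. Circles, squares and triangles are replicates 1, 2 and 3; replicate 1 had the lowest Ddr2 of its group in both groups (6.42 and 4.84 CPM).

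Libraries of 1 group differed widely. The first principal component held 50.1% of the variance and set the library labelled shDdr2 1 (-85.2) apart, with the other 5 between -16.3 and 45.7. The second held 22.2% and set control 1 (-55.7) apart. The library labelled shDdr2 1 had low stromal lists, with the collagen list 1.33 log2 units below its mean over libraries (deviation -1.33), the highest keratinocyte list (deviation 1.67), a TMM factor of 0.867 and 5.39% of counts in ribosomal protein genes. Control 1 had low interferon response (-1.13) and MHC class I (-1.41) lists, a high erythrocyte list (3.12), a low skeletal muscle list (-4.70) and 4.45% mitochondrial counts.

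No single gene passed the edgeR test. Of 14498 genes, 0 were called higher and 0 lower, with a lowest adjusted p of 1.00, while 209 had an unadjusted p under 0.05, 144 of them higher and 65 lower in the libraries labelled shDdr2. The 209 genes are fewer than chance gives on average at this p, which is a share of 0.05 of the 14498 genes. The groups did not overlap in 626 genes (4.32%), where chance gives 10% if all 6 libraries are exchangeable, a value that ignores the pairing. DESeq2 on the same counts called 34 genes higher and 6 lower at an adjusted p under 0.05, and limma called 0 on voom weights and 0 on the deposited log2 values. The count at an unadjusted p under 0.05 was 1022 without the library labelled shDdr2 1 and 395 without that labelled shDdr2 3. There were 0 edgeR calls in either, with a lowest adjusted p of 0.0908 and 0.0849.

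Of the 5 genes next by p on the higher side, 1 (Tnni2) belongs to the fixed skeletal muscle list, which does not hold every muscle gene. Mustn1, a nuclear protein of the musculoskeletal system (chromosome 14, 30879200 to 30881610), was at 0.949 ± 0.636 and 16.9 ± 10.6 CPM in control tumours and those labelled shDdr2, a log2 fold change of 4.16 (SE 0.68). Pdk4, a kinase that inhibits pyruvate dehydrogenase (chromosome 6, 5483351 to 5496309), was at 0.555 ± 0.227 and 17.3 ± 18.03 CPM, a log2 fold change of 4.95 (SE 0.87). Efemp1, an extracellular matrix glycoprotein (chromosome 11, 28853204 to 28926743), was at 7.59 ± 1.71 and 27.1 ± 9.31 CPM, a log2 fold change of 1.84 (SE 0.34). Tnni2, the fast skeletal troponin I (chromosome 7, 142441808 to 142444410), and Sh3bgr (chromosome 16, 96200450 to 96228935) had log2 fold changes of 3.56 (SE 0.69) and 3.96 (SE 0.80). All values are means ± SD of 3 libraries per group. DESeq2 called these 5 genes, with adjusted p from 4.72e-07 for Mustn1 and Pdk4 to 0.00116 for Efemp1.

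Of the 5 genes next by p on the lower side, 1 (Cxcl2) belongs to a fixed list, that of chemokines. Alox12, an arachidonate lipoxygenase (chromosome 11, 70241457 to 70255353), was at 13.4 ± 4.202 CPM in control tumours and 3.05 ± 0.245 CPM in those labelled shDdr2, a log2 fold change of -2.13 (SE 0.34). Muc1, a membrane mucin of epithelia (chromosome 3, 89229057 to 89233381), was at 27.3 ± 3.94 and 11.8 ± 2.66 CPM, a log2 fold change of -1.21 (SE 0.26). Cxcl2, a chemokine that attracts neutrophils (chromosome 5, 90903871 to 90905938), was at 64.3 ± 36.9 and 16.8 ± 4.75 CPM, a log2 fold change of -1.94 (SE 0.43). Il13ra2, a decoy receptor for interleukin 13 (chromosome X, 147383476 to 147429192), and Nupr1, a stress-induced nuclear protein (chromosome 7, 126623249 to 126630861), had log2 fold changes of -2.29 (SE 0.54) and -1.05 (SE 0.25). All values are means ± SD of 3 libraries per group. DESeq2 called Alox12 (adjusted p = 1.14e-05), Muc1 (0.0112), Cxcl2 and Il13ra2 (both 0.0142), but not Nupr1.

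**Figure D2:**
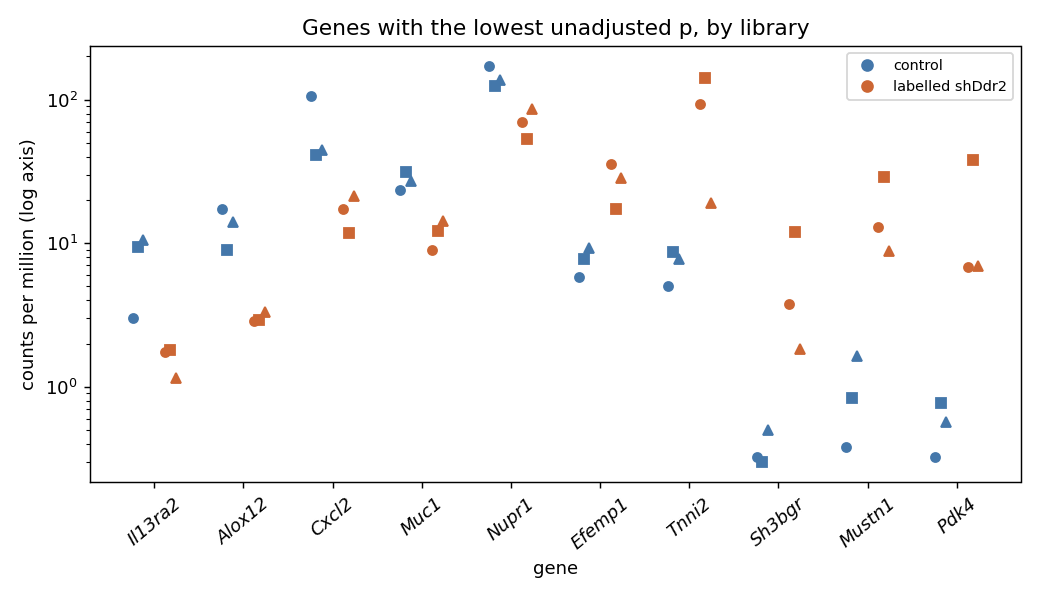
CPM, on a log axis, of the 5 genes with the lowest unadjusted p in each direction, by library; circles, squares and triangles are replicates 1, 2 and 3 of control tumours and of those labelled shDdr2. The groups do not overlap for any of the 10 genes, which were chosen for that, and none passed the edgeR test.

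Of the 28 gene lists tested with camera, 5 were called higher and 6 lower in the libraries labelled shDdr2 with the preset correlation. With a correlation estimated per list, 0 lists were called, and fry, which asks whether a list's genes move 1 way on balance, also called 0. When any 1 library was left out, the skeletal muscle, chemokine and hypoxia lists kept their call with the preset correlation. The other 8 did not. An estimated correlation gave 0 calls in each of these runs. The preset test also called 6 to 20 lists in other splits of the 6 libraries, so a kept call does not show that a list differs by shRNA.

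Skeletal muscle genes were higher in the libraries labelled shDdr2. The list mean was 1.21 ± 1.99 log2 CPM in control tumours and 6.02 ± 1.48 in those labelled shDdr2 (SD, n = 3), a difference of 4.81. All 12 tested members had higher values, 11 of them without overlap between the groups. Adjusted over the list alone, 11 of 12 passed the edgeR test, against 0 adjusted over all genes. The list test gave adjusted p = 7.45e-35 with the preset correlation and adjusted p = 0.254 with an estimated correlation. Ckm, muscle creatine kinase, was at 1.73 ± 1.46 and 113 ± 113 CPM, and Mylpf, a fast muscle myosin light chain, at 7.24 ± 5.26 and 114 ± 77.5 CPM. The most abundant members were Acta1, skeletal alpha-actin, at 19.4 ± 20.3 and 422 ± 401 CPM, and Myh4, a fast myosin heavy chain, at 2.64 ± 3.69 and 319 ± 385 CPM. Members of the list took 0.00103%, 0.00758% and 0.0120% of the counts in control 1 to 3, and 0.0906%, 0.344% and 0.0461% in the libraries labelled shDdr2 1 to 3.

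Chemokine and myeloid growth factor genes were called lower in the libraries labelled shDdr2. The list mean was 4.66 ± 0.0656 and 4.16 ± 0.326 log2 CPM (SD, n = 3), a difference of -0.51, and 20 of 28 tested members had lower values. The list's adjusted p was 1.98e-07, against adjusted p = 0.254 with an estimated correlation, and 0 members passed the edgeR test adjusted over the list alone. Besides Cxcl2, Csf3, the growth factor of granulocytes, was at 2.32 ± 1.16 and 0.457 ± 0.352 CPM, and Cxcl3 at 157 ± 102 and 54.8 ± 17.3 CPM. Neutrophil genes were also called lower, by -0.55 on the log2 scale with 8 of 12 members lower (adjusted p = 1.84e-04, and adjusted p = 0.463 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils and monocytes, was at 34.4 ± 18.5 and 11.8 ± 5.84 CPM, Il1b, which encodes interleukin 1 beta, at 39.5 ± 4.94 and 24.9 ± 6.37 CPM, and Clec4e at 7.50 ± 1.73 and 4.37 ± 1.89 CPM. Cxcl3 and S100a9 had log2 fold changes of -1.52 and -1.54, but -0.84 and -1.001 without control 1, and Clec4e had -0.78, but -1.19 without the library labelled shDdr2 3. No neutrophil member passed adjusted over the list alone (0 of 12), and the call was lost without the library labelled shDdr2 2 (-0.31, adjusted p = 0.0999).

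Hypoxia and glycolysis genes were called lower in the libraries labelled shDdr2, with means of 7.98 ± 0.0796 and 7.66 ± 0.166 log2 CPM (SD, n = 3). The difference was -0.32, and 18 of 20 members had lower values (adjusted p = 3.18e-07, and adjusted p = 0.280 with an estimated correlation). Adm, which encodes adrenomedullin, was at 81.8 ± 9.08 and 46.8 ± 19.3 CPM, Car9, a carbonic anhydrase, at 14.7 ± 3.68 and 8.90 ± 2.72 CPM, and Ankrd37 at 37.6 ± 9.61 and 22.2 ± 8.504 CPM. Adm differed by -0.81, but by -0.51 without the library labelled shDdr2 1, and Ankrd37 by -0.76, but by -0.48 without that labelled shDdr2 2. None passed adjusted over the list alone (0 of 20).

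Urothelial and epithelial genes were called lower, from 7.75 ± 0.269 to 7.24 ± 0.458 log2 CPM (SD, n = 3), a difference of -0.52 with 14 of 18 members lower and a median member at -0.27. The adjusted p was 4.43e-05, and adjusted p = 0.280 with an estimated correlation; 0 members passed over the list alone. Pparg, a nuclear receptor active in urothelial differentiation, was at 12.7 ± 3.58 and 3.81 ± 1.68 CPM, the tight junction gene Cldn4 at 364 ± 112 and 220 ± 21.1 CPM, and the keratin Krt18 at 92.2 ± 24.9 and 58.4 ± 19.2 CPM. DESeq2 called Pparg (adjusted p = 0.0492). Cldn4 differed by -0.73, but by -0.43 without control 1, and Krt18 by -0.66, but by -0.411 without control 1 and -0.409 without the library labelled shDdr2 1. Without the library labelled shDdr2 1, which stands apart and has the lowest value of this list, the difference was -0.26 and the call was lost (adjusted p = 0.132).

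Proliferation genes were called higher, by 0.23 on the log2 scale, with 22 of 22 members higher (adjusted p = 1.89e-05, and adjusted p = 0.519 with an estimated correlation). The mitotic kinases Bub1 and Bub1b were at 34.0 ± 3.00 and 43.5 ± 8.18 CPM and at 45.5 ± 6.47 and 57.4 ± 10.1 CPM, and the kinesin Kif20a at 34.9 ± 4.199 and 41.6 ± 2.46 CPM (SD, n = 3). Bub1 differed by 0.35, but by 0.21 without the library labelled shDdr2 1, and Bub1b by 0.34, but by 0.21 without that labelled shDdr2 2. None passed adjusted over the list alone (0 of 22). The difference was 0.10 without control 1 (adjusted p = 0.139) and 0.19 without the library labelled shDdr2 1 (adjusted p = 0.0521), which ended the call, and 0.16 and 0.35 without those labelled shDdr2 2 and 3, which did not.

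Mast cell genes were called lower by -0.66 on the log2 scale, with 7 of 7 members lower (adjusted p = 4.74e-04, and adjusted p = 0.463 with an estimated correlation). Fcer1a, a chain of the IgE receptor, was at 2.20 ± 1.47 and 0.937 ± 0.780 CPM, Hdc, which makes histamine, at 6.24 ± 1.57 and 3.74 ± 2.48 CPM, and the protease Mcpt4 at 6.59 ± 3.98 and 3.84 ± 1.59 CPM (SD, n = 3). The call was lost without control 3 (-0.32, adjusted p = 0.177) and without the library labelled shDdr2 1 (-0.49, adjusted p = 0.137). Fcer1a differed by -1.20, but by -0.51 without control 3 and by -2.13 and -0.77 without those labelled shDdr2 2 and 3. Mcpt4 differed by -0.77, but by -0.22 without control 3 and -0.49 without that labelled shDdr2 3, and Hdc by -0.73, but by -0.47 and -1.43 without those labelled shDdr2 2 and 3. Immediate early and heat shock genes were called lower by -0.17, with 13 of 18 members lower (adjusted p = 0.00869, and adjusted p = 0.519 with an estimated correlation). The transcription factor gene Junb was at 434 ± 51.3 and 292 ± 36.5 CPM and Ier3 at 278 ± 44.5 and 161 ± 85.6 CPM, while Nr4a1 was at 33.2 ± 12.8 and 50.04 ± 9.58 CPM. Ier3 differed by -0.785, but by -1.31 without the library labelled shDdr2 3, and Nr4a1 by 0.59, but by 0.34 without control 1. The list difference was -0.04 without control 2 (adjusted p = 0.5004) and -0.12 without the library labelled shDdr2 1 (adjusted p = 0.115), which ended the call, and -0.27 without control 1. Adjusted over the list alone, 0 members of either list passed.

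Markers of 3 other cell types were called higher in the libraries labelled shDdr2, with 0 members of these lists past the edgeR test adjusted over the list alone. B and plasma cell genes differed by 1.12 on the log2 scale, with 6 of 6 tested members higher (adjusted p = 0.0175, and adjusted p = 0.565 with an estimated correlation). Igkc, the immunoglobulin kappa constant region, was at 24.0 ± 29.8 and 47.1 ± 51.0 CPM, Cd22 at 1.38 ± 1.29 and 2.02 ± 1.13 CPM, and Mzb1 at 0.448 ± 0.344 and 0.770 ± 0.820 CPM (SD, n = 3). That difference was 0.08 without control 1 (adjusted p = 0.947), 0.60 without the library labelled shDdr2 2 (adjusted p = 0.195) and 1.55 without that labelled shDdr2 1 (adjusted p = 0.0987), all of which ended the call, and 1.84 without control 3. Igkc differed by 0.98, but by 0.40 and 2.71 without control 1 and 3, and by 1.47 and -0.39 without the libraries labelled shDdr2 1 and 2. Mzb1 differed by 0.83, but by 0.30 and 1.28 without control 1 and 3, and by -0.57 and 1.298 without those labelled shDdr2 2 and 3. Cd22 differed by 0.56, but by 0.20, 1.65 and 0.24 without control 1, 2 and 3, and by 0.93 and 0.145 without those labelled shDdr2 1 and 2.

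Keratinocyte genes differed by 0.61, with 9 of 10 members higher and a median member at 1.01 (adjusted p = 0.0254, and adjusted p = 0.692 with an estimated correlation). Krt10, a keratin of differentiated epidermis, was at 293 ± 104 and 653 ± 651 CPM, Kprp at 2.14 ± 1.39 and 10.3 ± 5.86 CPM, and Lce1a1, a cornified envelope gene, at 0.474 ± 0.290 and 3.36 ± 4.90 CPM (SD, n = 3). Without the library labelled shDdr2 1 the list difference was -0.07 and the call was lost (adjusted p = 0.339), Krt10 was at -0.07 against 1.16 with all libraries, and Lce1a1 at 0.15 against 2.775. The list difference was 0.95 and 1.17 without those labelled shDdr2 2 and 3, and a stricter count filter ended the call at 0.51 (adjusted p = 0.0705). Adipocyte genes differed by 0.86, with 5 of 5 members higher but a median member at 0.25 (adjusted p = 0.0449, and adjusted p = 0.407 with an estimated correlation). Car3, a carbonic anhydrase of fat and muscle, was at 1.63 ± 1.72 and 12.9 ± 13.2 CPM, Cfd at 0.4996 ± 0.276 and 1.33 ± 0.936 CPM, and Fabp4, the adipocyte fatty acid binding protein, at 27.4 ± 7.67 and 32.8 ± 16.6 CPM (SD, n = 3). The adipocyte call was lost with the replicate block (0.86, adjusted p = 0.05001) and on voom weights (0.95, adjusted p = 0.0575). It was also lost without control 1 (0.70, adjusted p = 0.0560) and without control 3 (0.92, adjusted p = 0.0597). The same held without the library labelled shDdr2 1 (0.72, adjusted p = 0.529) or 3 (0.85, adjusted p = 0.239). Car3 had the largest difference of the list (3.004, but 1.75 without that labelled shDdr2 2), and the mean of the other 4 members differed by 0.27. Cfd differed by 1.37, but by 0.67 without the library labelled shDdr2 1. Fabp4 differed by 0.25, but by 0.08 and 0.47 without control 1 and 2, and by -0.11, 0.61 and 0.17 without those labelled shDdr2 1, 2 and 3.

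**Figure D3:**
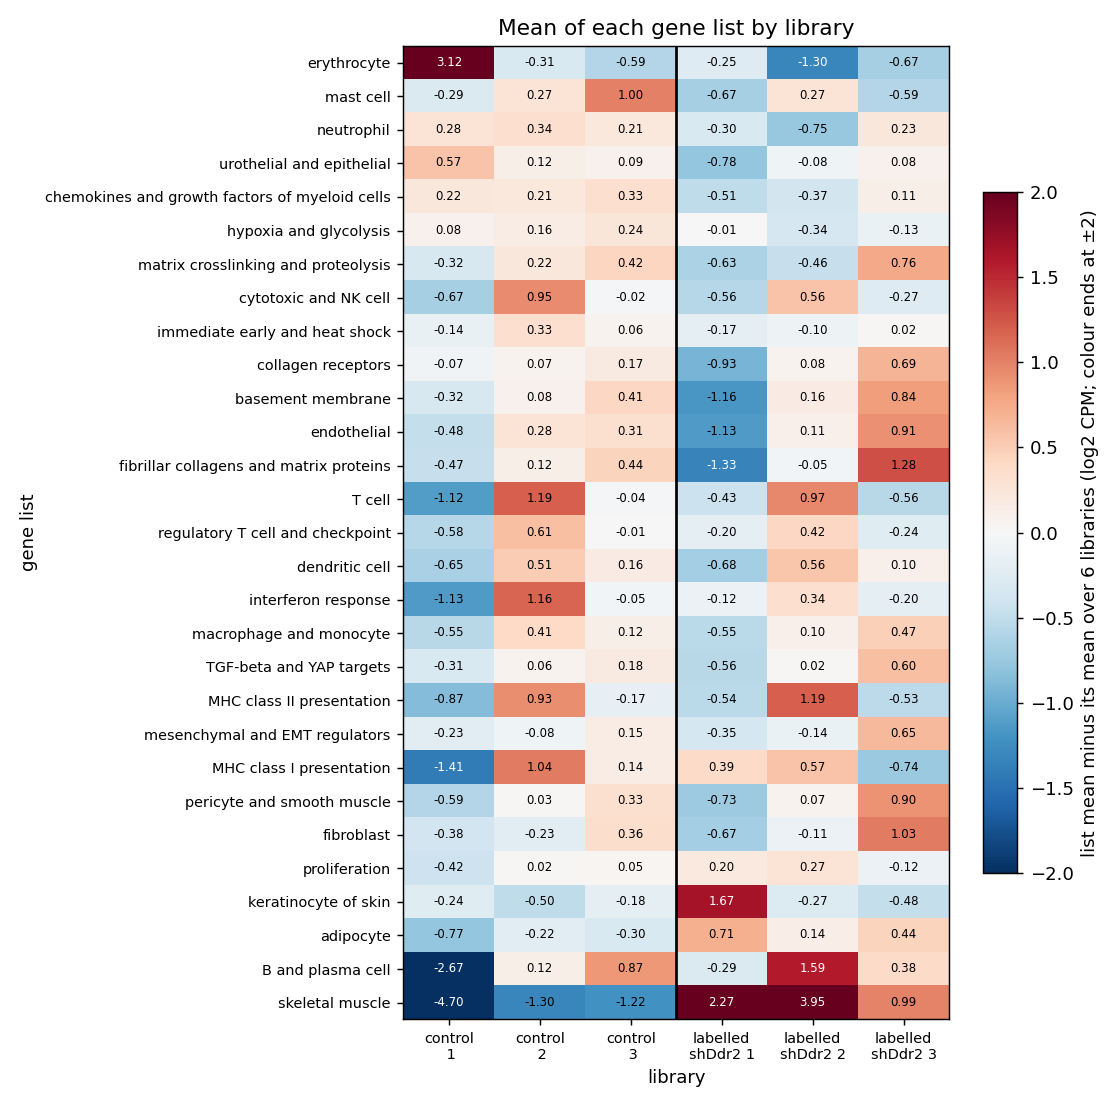
Mean log2 CPM of each of the 29 gene lists in each library, as the deviation from the list's mean over the 6 libraries, ordered by the difference between groups; colours end at 2 and the numbers give the deviation. The skeletal muscle list is between 0.99 and 3.95 in the libraries labelled shDdr2 and between -4.70 and -1.22 in control libraries, while the collagen list spans -1.33 to 1.28 within the libraries labelled shDdr2.

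The matrix and stromal lists were not called with all 6 libraries, and the libraries labelled shDdr2 spread widely in them. Fibrillar collagens and matrix proteins were at 7.51 ± 0.459 log2 CPM in control tumours and 7.44 ± 1.31 in those labelled shDdr2 (SD, n = 3), a difference of -0.06 with 18 of 20 fitted members above 0. Dcn, the proteoglycan decorin, was at 116 ± 10.1 and 141 ± 35.5 CPM. Differences were -0.21 for matrix crosslinking and proteolysis (P4ha3, a collagen prolyl hydroxylase subunit, at 19.1 ± 4.33 and 30.6 ± 3.96 CPM) and -0.11 for basement membrane (Lama4, a laminin chain, at 34.5 ± 9.25 and 47.2 ± 40.7 CPM). They were -0.11 for collagen receptors (Itga2, an integrin chain, at 42.5 ± 18.3 and 25.7 ± 14.7 CPM) and 0.16 for fibroblasts (Pi16 at 9.62 ± 6.37 and 28.4 ± 30.8 CPM). Pericyte and smooth muscle genes differed by 0.16 (Des, desmin, at 19.7 ± 17.5 and 171 ± 143 CPM) and endothelial genes by -0.07 (Tek, an angiopoietin receptor, at 3.08 ± 0.636 and 5.84 ± 3.91 CPM). Mesenchymal regulators differed by 0.11 (Cdh11, a cadherin, at 39.4 ± 5.11 and 60.2 ± 28.6 CPM) and TGF-beta and YAP targets by 0.05 (Ankrd1 at 5.29 ± 3.61 and 21.2 ± 11.5 CPM). Pi16 went from 1.56 to 0.23 on the log2 scale without the library labelled shDdr2 3, Tek from 0.92 to 0.35, Cdh11 from 0.61 to 0.15, Dcn from 0.28 to 0.11 and Itga2 from -0.73 to -1.28. Dcn was at 0.47 and Itga2 at -0.43 without that labelled shDdr2 1, and Itga2 at -0.48 without control 1. DESeq2 called Des higher (adjusted p = 0.0141), a gene that skeletal muscle also expresses.

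The direction of the stromal lists depended on the libraries used. Without the library labelled shDdr2 1, the collagen (0.59, adjusted p = 3.25e-04), basement membrane (0.44, adjusted p = 0.00453), pericyte (0.56, adjusted p = 0.0485) and endothelial (0.47, adjusted p = 6.87e-04) lists were called higher. Without the library labelled shDdr2 3 the same lists were called lower, by -0.72 (adjusted p = 1.70e-06), -0.56 (0.00106), -0.25 (0.00690) and -0.55 (0.00263). The collagen receptor (-0.49, adjusted p = 0.0229), crosslinking (-0.65, adjusted p = 4.71e-05), fibroblast (-0.31, adjusted p = 0.0261) and TGF-beta (-0.25, adjusted p = 0.00905) lists were then also called lower. Lists not called also moved: without the first of these libraries the collagen receptor, crosslinking, fibroblast, mesenchymal and TGF-beta lists were at 0.32, 0.04, 0.54, 0.31 and 0.34, and without the second the mesenchymal list was at -0.19. Leaving out that labelled shDdr2 2 gave -0.18 for collagen receptors, -0.04 for crosslinking, -0.22 for basement membrane, 0.20 for mesenchymal, 0.26 for fibroblast and -0.15 for endothelial genes. Leaving out control 1 gave -0.30 for collagen, -0.29 for basement membrane, 0.03 for mesenchymal, 0.03 for fibroblast, -0.08 for pericyte, -0.32 for endothelial and -0.08 for TGF-beta genes. Leaving out control 2 gave -0.02 for collagen, 0.09 for fibroblast, 0.05 for endothelial and 0.09 for TGF-beta genes. Leaving out control 3 gave -0.06 for collagen receptors, 0.14 for collagen, -0.06 for crosslinking, 0.06 for basement membrane, 0.21 for mesenchymal, 0.38 for fibroblast, 0.36 for pericyte, 0.06 for endothelial and 0.14 for TGF-beta genes. The crosslinking list was called lower without control 1 too (-0.42, adjusted p = 0.0148), and Lama4, at 0.45 with all libraries, was at -0.48 without the library labelled shDdr2 3, 0.89 without that labelled shDdr2 1 and 0.27 without control 1. All of the calls with a library left out used camera with the preset correlation of 0.01, far below the estimated correlations, which with all libraries were 0.893 for the collagen, 0.849 for the basement membrane, 0.764 for the endothelial and 0.670 for the pericyte list. With an estimated correlation 0 of these lists were called, with adjusted p = 0.720 for the 4 lists without the library labelled shDdr2 1, 0.515 for the 8 without that labelled shDdr2 3 and 0.784 for crosslinking without control 1.

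Lymphoid, antigen presentation and interferon lists were not called with all 6 libraries either. Differences were -0.02 for T cells (Cd27 at 0.888 ± 0.560 and 1.23 ± 0.507 CPM), -0.18 for cytotoxic and NK cells (Eomes at 7.76 ± 3.50 and 4.75 ± 0.899 CPM) and -0.01 for regulatory T cell and checkpoint genes (Havcr2, the checkpoint receptor TIM-3, at 22.2 ± 9.31 and 13.8 ± 0.778 CPM). They were 0.02 for macrophages and monocytes (Lyz2, lysozyme, at 280 ± 10.8 and 414 ± 39.99 CPM) and -0.01 for dendritic cells (Fscn1 at 275 ± 67.8 and 226 ± 26.9 CPM). MHC class I presentation genes differed by 0.15 (Psme2, a proteasome activator subunit, at 46.4 ± 15.7 and 59.2 ± 35.5 CPM) and MHC class II by 0.08 (Ctss, cathepsin S, at 199 ± 92.1 and 222 ± 73.3 CPM). Interferon response genes differed by 0.02 (Oasl1 at 11.8 ± 0.770 and 8.22 ± 3.54 CPM). The erythrocyte list, with 4 tested members and no test, differed by -1.48, but by -0.28 without control 1 (Alas2, the heme synthesis enzyme of red cells, at 8.90 ± 11.8 and 1.51 ± 0.0124 CPM). Values are means ± SD of 3 libraries per group. Without control 1, Alas2 went from -2.56 to -0.45 on the log2 scale, Havcr2 from -0.69 to -0.27, Fscn1 from -0.28 to -0.45 and Ctss from 0.15 to -0.11. Without control 2, Eomes went from -0.71 to -0.37, Cd27 from 0.48 to 0.99, Psme2 from 0.35 to 0.66 and Ctss to 0.56. Without control 3, Fscn1 was at -0.13, Cd27 at 0.08 and Psme2 at 0.21. Without the library labelled shDdr2 1, Oasl1 went from -0.52 to -0.33, and Cd27 was at 0.77, Psme2 at -0.23 and Ctss at 0.35. Without that labelled shDdr2 2, Cd27 was at 0.28 and Ctss at -0.13, and without that labelled shDdr2 3, Psme2 was at 0.67 and Oasl1 at -0.93. Over all 17 lists not called the adjusted p ranged from 0.398 to 0.863. In 10 of them the mean of log2 CPM, the median of fitted log2 fold changes and the test were not of 1 sign.

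Control 1 was low and control 2 high in the lymphoid, macrophage, dendritic cell, antigen presentation and interferon lists. These libraries decided the direction of several of these lists. The neutrophil list was not low in control 1 (deviation 0.28). Without control 1 the T cell (-0.57, adjusted p = 2.96e-04), interferon response (-0.53, adjusted p = 5.25e-06), MHC class I (-0.51, adjusted p = 3.47e-05), cytotoxic (-0.54, adjusted p = 0.00358), checkpoint (-0.29, adjusted p = 0.0134) and dendritic cell (-0.29, adjusted p = 0.0174) lists were called lower. Without control 2 the T cell (0.57, adjusted p = 8.22e-06), interferon response (0.60, adjusted p = 3.35e-07), MHC class I (0.70, adjusted p = 8.90e-06), MHC class II (0.56, adjusted p = 0.00156) and macrophage (0.22, adjusted p = 0.00195) lists were called higher. Without the library labelled shDdr2 2 the T cell (-0.50, adjusted p = 0.00986), cytotoxic (-0.50, adjusted p = 0.0425), dendritic cell (-0.29, adjusted p = 0.0425) and MHC class II (-0.50, adjusted p = 0.00575) lists were called lower. The macrophage list was called higher without the library labelled shDdr2 1 (0.29, adjusted p = 0.0121), and MHC class I without that labelled shDdr2 3 (0.55, adjusted p = 0.0110). All of these calls used camera with the preset correlation, and with an estimated one 0 were called (adjusted p from 0.491 to 0.799). Lists not called moved as well. Leaving out control 1 gave -0.24 for macrophage and -0.27 for MHC class II genes, and leaving out control 2 gave 0.25 for cytotoxic, 0.29 for checkpoint and 0.24 for dendritic cell genes. Leaving out control 3 gave -0.04 for T cell, -0.02 for checkpoint, 0.08 for macrophage, 0.07 for dendritic cell, 0.25 for MHC class I, 0.05 for MHC class II and -0.01 for interferon response genes. Among the libraries labelled shDdr2, leaving out number 1 gave 0.20 for T cell, 0.06 for cytotoxic, 0.08 for checkpoint, 0.34 for dendritic cell, -0.01 for MHC class I, 0.39 for MHC class II and 0.08 for interferon response genes. Leaving out number 2 gave -0.23 for checkpoint, -0.03 for macrophage, -0.10 for MHC class I and -0.15 for interferon response genes, and leaving out number 3 gave 0.26 for T cell, -0.09 for cytotoxic, 0.10 for checkpoint, -0.22 for macrophage, -0.02 for dendritic cell, 0.38 for MHC class II and 0.12 for interferon response genes.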

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

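The 0 edgeR calls in each direction held under every scaling, filter and fit tried and without any 1 library, with 170 to 1033 genes at an unadjusted p under 0.05, and limma also gave 0, whereas DESeq2 called 34 genes higher and 6 lower, for which the cause was not tested. The replicate block left 0 gene calls, with Ddr2 at 0.10 (0.08 by limma on the deposited log2 values, 0.16 with the collagen covariate), and changed no list call other than that of adipocytes. Ddr2 ranged from -0.28 to 0.71 when 1 library was left out.

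The 5 lists called higher and 6 lower became 0 and 0 with an estimated correlation, and 0 and 0 with fry. The stricter filter gave 3 higher lists, since adipocytes then had too few members and keratinocytes lost their call. Leaving out replicate 1 of both groups, chosen after seeing the data, gave 2 higher and 5 lower lists, and the adipocyte list could not be tested. It ended the urothelial (-0.11, adjusted p = 0.534), proliferation (0.03, 0.521), B cell (0.48, 0.521), neutrophil (-0.54, 0.0834) and keratinocyte calls, and the collagen list was called higher (0.33, adjusted p = 0.0324) and the MHC class I list lower (-0.69, adjusted p = 0.00336; both 0.886 with an estimated correlation). Leaving out 1 library gave 2 to 10 higher lists and 3 to 14 lower ones, and 0 in each case with an estimated correlation, also chosen after seeing the data. The causes were otherwise not tested.

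With 1 library left out, the keratinocyte list ranged from -0.0659 to 1.17, and log2 fold changes ranged from -0.13 to 0.56 for Ctss, -0.0698 to 1.57 for Krt10, -0.23 to 0.67 for Psme2, -0.11 to 0.61 for Fabp4, -0.57 to 1.298 for Mzb1, -0.39 to 2.71 for Igkc, -0.0725 to 0.32 for Ddr1 and -0.48 to 0.89 for Lama4. Without replicate 1 of both groups, Psme2 was at -0.38, Fabp4 at -0.30 and the keratinocyte list at -0.12, and the cause was not tested. Over all alternatives, values of named genes, Ddr2 included, kept direction and side of the threshold 1165 times, passed it 13 times (all with DESeq2) and reversed 13 times (2 of them Ddr2), while called lists kept both 106 times, lost the call 44 times and reversed 2 times. A planned repeat on counts from the files of single samples was not run, since these hold log2 values.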

Other observations

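The tests of the muscle genes outside the fixed list, of Ddr2 against the collagen and other lists, within pairs too, and of Ddr2 minus the fibroblast list were chosen only after related values had been seen, as were the fits without replicate 1 of both groups and with the collagen covariate. The use of simulated and unadjusted counts in reading these fits, and the use of the SE in reading Ddr2 minus the fibroblast list, were also settled after the results were seen.

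Besides the lists, the 34 genes that DESeq2 called higher held 14 members of the fixed or the further skeletal muscle list. That count covers list members only, and muscle genes outside the lists are not in it. Mustn1 and Des, for example, were called higher and are on neither list. Further muscle genes, chosen after some of their values had been seen, had higher means in the libraries labelled shDdr2 in 14 of 14 tested, with a median log2 difference of 4.07 for the 7 whose values had been seen and 2.28 for the 7 not seen. Among the 7 not seen before, Ttn and Neb, giant proteins of the sarcomere, differed by 3.40 and 3.51, Mb, myoglobin, by 1.21 and Cox7a1 by 0.35. None of the 4 passed the edgeR test, and DESeq2 called Neb of these (adjusted p = 0.0142).

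Skeletal muscle genes had higher values in the libraries labelled shDdr2 in 12 of 12 tested, called with the preset correlation (adjusted p = 7.45e-35) but not with an estimated one (adjusted p = 0.254) or fry (adjusted p = 0.590), and 0 of 12 passed edgeR over all genes, with 11 at an unadjusted p under 0.05. Scaling by TMM is argued against, since its factors, from 0.867 to 1.05, are too near 1 to make such a difference. With library totals only the list differed by 4.77 on the log2 scale, an outcome that these factors fixed in advance. Host muscle tissue in the samples may be a source, but the values do not decide it. Further muscle genes followed the fixed list over the 6 libraries with a median r of 0.948. It was 0.915 over the 7 not seen before (from -0.09 for Cox7a1 to 0.968). This r includes the difference between the groups, so any cause that raised muscle genes together would give a high r. Of the 24 further muscle genes, 10 were not among the tested genes. Abundant muscle transcripts such as Acta1 and Myh4 were at 422 and 319 CPM in the libraries labelled shDdr2. The labels do not say where the tumours grew or how they were cut out, and an effect of the shRNA on muscle genes stays open, as untested.

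Ddr2 was not lower in the libraries labelled shDdr2, and over the 6 libraries it followed the mean of the collagen list (Pearson r = 0.925, exact permutation p = 0.00278, adjusted over 6 relations 0.00833; Spearman rho = 0.943, exact p = 0.0167, adjusted 0.0250), with r = 0.879 without the 2 libraries farthest from the median. These p-values and those of the other lists treat the 6 libraries as exchangeable although same-numbered ones were taken as pairs: an exact permutation test with exchanges within pairs only gave p = 0.25 for the collagen list and 0.125 to 1 for the others, where 0.125 is the smallest possible, and r within pairs was 0.905 for the collagen list, with differences of 1 sign in 2 of 3 pairs. The share of stroma may set the Ddr2 level in whole tumours, but these correlations cannot tell stroma from tumour cells as the source. The series describes NA13 as a line with high DDR2 expression. For the fibroblast, endothelial, pericyte, urothelial and T cell lists r was 0.842, 0.966, 0.955, 0.304 and 0.442 (adjusted exact p 0.0562, 0.00833, 0.00833, 0.590 and 0.433; raw 0.0375, 0.00417, 0.00139, 0.590 and 0.361), rho was 1, 0.943, 1, 0.0286 and 0.0857 (adjusted exact p 0.00833, 0.0250, 0.00833, 1 and 1), and r without the 2 farthest libraries was 0.930, 0.958, 0.974, 0.119 and 0.446. Ddr2 minus the fibroblast list mean differed by -0.0762 (SE 0.54, exact permutation p = 0.8), but this SE and p ignore the pairing. The values were -1.41, -0.20 and -0.49 in control 1 to 3. They were -1.51, -0.13 and -0.69 in the libraries labelled shDdr2 1 to 3. The latter were thus lower for numbers 1 and 3 and higher for number 2, and no paired test was run. A knockdown confined to tumour cells and its absence therefore cannot be told apart, and a wrong label stays open.

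No gene passed the edgeR threshold. A spread of stroma within the groups, and 1 library of each group that stands apart, were each examined as the whole cause. With the collagen list mean as a covariate there were 0 calls, and 0 without replicate 1 of both groups. Both were below the bound of 10 set beforehand. These 0 calls cannot decide either cause, since 6 libraries or fewer give a loose estimate of the spread. On simulated counts these fits called 39.7% and 47.1% of genes changed by 1 on the log2 scale. With all libraries and no covariate 10.3% were called. At 2 the values were 95.5% and 86.4% against 81.8%, and at 3 they were 97.0% in each. This recovery may not carry over to the real counts. There, with all libraries, the skeletal muscle list differed by 4.81 and 0 of 12 members passed. At an unadjusted p under 0.05 the fits gave 377 and 1033 genes against 209. Leaving out control 1 alone gave 195, and leaving out the library labelled shDdr2 1 alone gave 1022. A part of the stroma and of the library labelled shDdr2 1 in the spread thus stays open, while leaving out control 1 alone did not raise the count. The 377, 209 and 195 are below the share of 0.05 that chance gives on average. An effect of the shRNA below the reach of the test also stays open, untested. Of the 10 splits of the 6 libraries, too few for a share under 0.05, 8 gave as many list calls as the real 11, the highest other giving 20, and all 10 gave as many gene calls as the real 0 (highest other 1), which a real count of 0 fixes in advance. At an unadjusted p under 0.05, splits with control 1 and the library labelled shDdr2 1 on 1 side gave 606 to 2447 genes. The others besides the real split gave 86 to 598. The 3 others that part all 3 same-numbered pairs gave 6 to 16 lists and the 6 that part 1 pair gave 11 to 20. Among splits other than the real one, the muscle list difference largest in size was 3.34, against 4.81 in the real split. It was -0.44 for the chemokine, -0.51 for the urothelial and 0.26 for the hypoxia list, against -0.51, -0.52 and -0.32. These differences are taken against the side that holds control 1.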
